A study of Mus musculus with 12 samples.

How the data were processed

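Fully grown mouse oocytes of 3 Marf1 genotypes (WT, GTMut and D272Mut) were profiled by RNA-seq, 4 libraries per genotype and 12 in all, with the genotype of each library taken from its label. Per the labels' protocols and the series' design text, total RNA was extracted from 80 oocytes per library, messenger RNA libraries were built with a fragmentation and random priming kit, and reads of 150 bp were taken from both fragment ends on a HiSeq X instrument. The labels contradict each other in places: the extraction text also names Smart-seq2 amplification, and the treatment text speaks of lysed ovaries where the design text speaks of collected oocytes. Whether the libraries of a genotype came from separate mice, and any batch or date, is not given in the sources used here.

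Per the series' design text and the submitters' processing notes, reads were trimmed, aligned to mm10 with TopHat2 2.0.13 and turned by the authors into FPKM values with Cufflinks 2.2.1. The deposited FPKM values are normalized to transcript length and library size. The authors also deposited log2 fold changes, p-values and q-values from cuffdiff for each pair of genotypes, which were used only for comparison. These deposited log2 ratios are the second genotype of a column title over the first, which was checked on the FPKM means. The header of the table lacks a name for its first column, so the columns were read by position. The table holds 24254 genes, and 1 further line that came without content was not analysed here. Reads of overlapping, antisense or near-identical genes can be split among them by such a pipeline, and strand-specific counting is not given in the sources used here, so these genes are marked as overlapping where named.

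FPKM values hold no totals. Relative depth was therefore estimated from genes under 0.3 FPKM in pairs of libraries, where the step of 1 fragment sets the ratio. The estimate used 65 library pairs, 61.4% of the low genes lay at the modal ratio, and the largest residual was 0.0015 on the log2 scale. Depth relative to GTMut replicate 4 was 0.613 to 0.944 in WT, 0.556 to 1 in GTMut and 0.444 to 0.836 in D272Mut, so the depth ranges of the genotypes overlap. The absolute depth is unknown, no counting interval can be given, and a gene listed at 0 is reported as such. Short small RNA genes (1285 in the table) took 47.8% to 91.4% of the summed FPKM of a library, because FPKM divides by a small length, so summed FPKM was not used to scale libraries.

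Values were analysed as log2(FPKM + 1) for genes with a maximum FPKM of at least 1 in any library, which left 12980 genes out of 19162 above 0 anywhere. The filter and the log scale follow the design text. All 12 libraries were fitted together with limma 3.58.1 in R 4.3.3 (9 residual degrees of freedom, empirical Bayes with an intensity trend), and the contrasts were GTMut against WT, D272Mut against WT and D272Mut against GTMut. Tests were two-sided, and an adjusted p is the limma p after Benjamini-Hochberg adjustment over the 12980 genes of a contrast, with 0.05 as the threshold. Marf1 and Ppp2cb were also tested with exact permutation of the libraries. Fold changes of genes listed at 0 are not printed. Correlations between libraries and between effects are across genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

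Gene lists were fixed before the data were examined. They covered the targeted gene, PP2A subunits and shugoshins, meiotic resumption and the cell cycle, cAMP and cGMP meiotic arrest, maternal effect genes with the subcortical complex, zona and oocyte-secreted factors with other oocyte genes, oocyte transcription factors and growth, maternal mRNA storage and translation, mRNA decay, the piRNA pathway and retrotransposon control, DNA damage response and repair, p53 targets and oocyte death, the interferon and cytosolic nucleic acid response, replication-dependent histones, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, the unfolded protein and heat shock response, immediate early genes, granulosa and cumulus markers, and other ovarian cell markers. The 19 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over 19 lists. Genes in the text were chosen by a rule written before the data were examined. It takes Marf1 and Ppp2cb always, and per contrast the 10 largest rises and 10 largest falls among genes past the threshold whose library groups do not overlap, skipping unnamed gene models. It adds up to 4 members past the threshold of each list, smallest p first, the 3 most abundant members of each marker list, and the 10 genes with the smallest p between the mutants. The rule gave 182 genes, 19 of which overlap another tested gene. Of these the text prints some members of each list, and a gene chosen by a contrast may be given in the others. The gene families of the 2-cell stage, the Id family and quantile normalization of lists and single genes were chosen after seeing the data.

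The gene model of each symbol was matched to GENCODE release M21 for mouse, which is on the same build as mm10: 95.6% of the tested genes had a matching symbol, and 99.6% of those lay on the same chromosome as in the deposited table. Coordinates in the text are those of GENCODE. The statistical steps were tested on simulated data for GTMut against WT with 12980 genes of which 200 were changed: 81.5% of genes changed 1.5-fold, 94.5% changed 2-fold and 99.5% changed 4-fold were recovered, with 6, 11 and 10 false calls, and an unchanged D272Mut gave 0 calls. The changed genes were drawn from those with a mean log2(FPKM + 1) over 1 in WT, and noise was independent between genes. These rates therefore do not describe low genes, factors shared within a library or data with 77.5% of genes called, as in GTMut.

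Alternatives, whose effects are given with the other observations, were other pseudocounts, no filter or a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, fits of only the compared genotypes, the replicate number as a block, no intensity trend, library weights, a 2-fold minimum, leaving out each library in turn, and the authors' calls. Correlations of the mutants' effects were repeated with WT split into 2 pairs of libraries, in each of 6 ways, and compared with 100 simulations of unchanged groups. These drew all 12 libraries around the WT gene means, with independent noise per gene and no factor shared between genes.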

Results

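RNA was sequenced from fully grown mouse oocytes at the germinal vesicle stage, the stage of arrest before meiosis resumes, in 3 genotypes of Marf1. MARF1 (meiosis regulator and mRNA stability factor 1) is an RNA-binding protein that oocytes need to resume meiosis, and its amino-terminal NYN domain is a ribonuclease fold. The genotypes were wildtype (WT), a gene trap of Marf1 (GTMut) and a mutant that the labels name D272 (D272Mut). Each was represented by 4 libraries of 80 oocytes from C57BL/6 mice of 3 weeks, taken 46 h after 5 IU of PMSG, a gonadotropin that drives follicle growth. Levels below are mean FPKM (fragments per kilobase of transcript, scaled to library size) ± SD of the 4 libraries of a genotype. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and carry the standard error of the limma fit. Relative sequencing depth, read from the FPKM worth of 1 fragment in low genes, differed 2.25-fold between the shallowest library (D272Mut replicate 1) and the deepest (GTMut replicate 4). The number of genes at an FPKM of at least 1 was 10741 ± 31 in WT, 11350 ± 48 in GTMut and 11339 ± 46 in D272Mut. Libraries of a genotype correlated with each other at 0.965 to 0.990 across genes. WT correlated with GTMut at 0.789 to 0.817 and with D272Mut at 0.827 to 0.844, and the mutants correlated with each other at 0.942 to 0.964.

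The targeted gene was read first, as a check of the labels. Marf1 lies on mm10 chromosome 16 (14109173 to 14163351, minus strand). It has 27 exons in the transcript used for exon numbers, the longest of the annotation's principal transcripts where a gene has any. Marf1 stood at 25.8 ± 0.63 FPKM in WT, 1.43 ± 0.13 in GTMut and 53.1 ± 1.0 in D272Mut. It was therefore lower in GTMut by a log2 fold change of -3.46 ± 0.05 and higher in D272Mut by 1.01 ± 0.05, with no overlap between the libraries of any pair of genotypes. A two-sided exact permutation test gave p = 0.0286 for each pair, the smallest value that the 70 arrangements of 8 libraries allow. Ppp2cb, which encodes a catalytic subunit of protein phosphatase 2A (chromosome 8, 33599625 to 33619441, plus strand), moved in the same direction in both mutants. It stood at 1.39 ± 0.33 FPKM in WT, 92.3 ± 3.5 in GTMut and 48.9 ± 4.0 in D272Mut, with exact permutation p = 0.0286 for each pair. Ppp2cb overlaps 1 other tested gene on the opposite strand, Ubxn8, and strand-specific counting is not stated, so reads from the overlap could belong to either gene. The extent of the overlap was not measured.

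**Figure D1:**
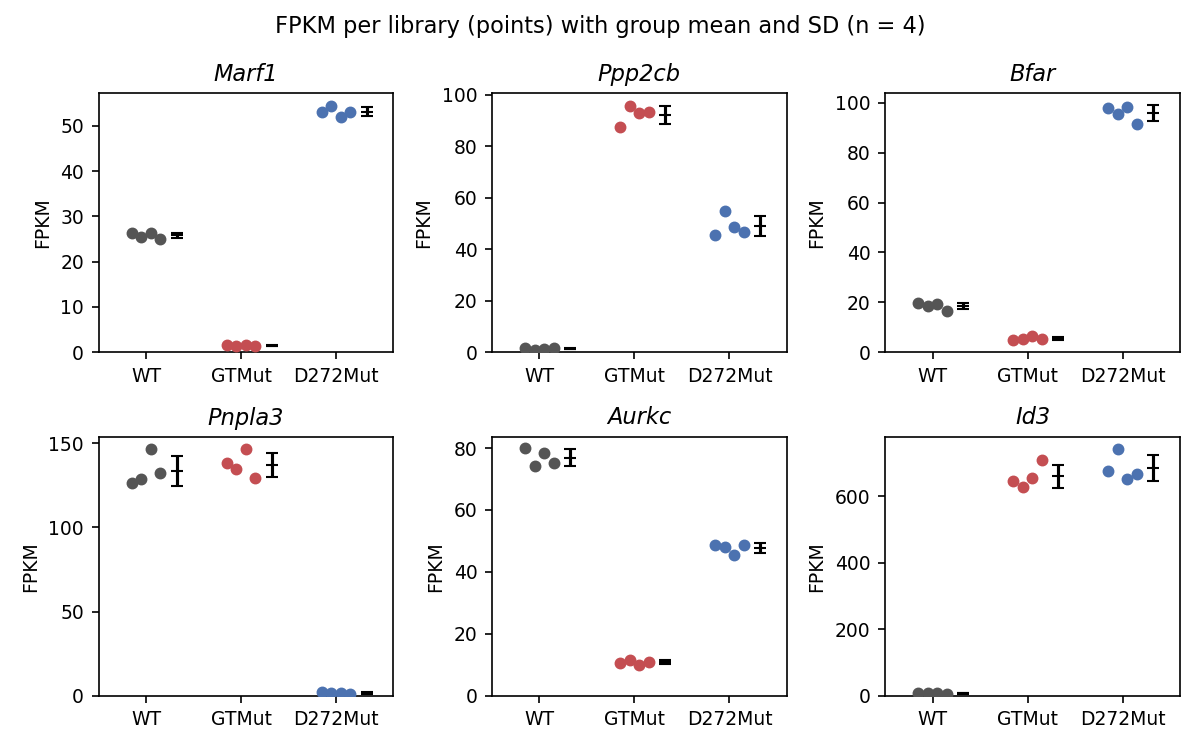
FPKM (vertical axes, linear and starting at 0) of 6 genes in WT, GTMut and D272Mut, with a point for each of the 4 libraries and the group mean with its SD beside them. Marf1 is at 1.43 in GTMut and 53.1 in D272Mut, Ppp2cb and Id3 are higher in both mutants, Bfar and Marf1 go in opposite directions in the mutants, and Pnpla3 is low in D272Mut only among the 3 genotypes.

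The comparison of GTMut with WT asks how the oocyte transcriptome differs when Marf1 is trapped. The genes with the largest rises were low in WT oocytes. Fzd5, a Wnt receptor, rose from 0.922 ± 0.18 to 255 ± 5.3 FPKM, and Dio3, the deiodinase that inactivates thyroid hormone, from 2.53 ± 0.90 to 447 ± 10. Id3, an inhibitor of basic helix-loop-helix transcription factors, rose from 6.88 ± 1.3 to 660 ± 35, and Tex19.2, a germline gene related to Tex19.1, from 5.49 ± 1.3 to 543 ± 36. The largest falls included Cdo1, the cysteine dioxygenase of taurine synthesis, from 148 ± 9.8 to 6.76 ± 1.8, and Slc39a8, a zinc and manganese transporter, from 23 ± 4.9 to 0.0397 ± 0.034.

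Of 12980 genes tested with limma, 4973 were higher and 5086 lower in GTMut at a Benjamini-Hochberg adjusted p under 0.05. At least 2-fold changes were more often rises, 2508 against 1247, and 210 genes rose at least 16-fold while 6 fell that far. Fam109a, Cdc42ep4 (an effector of Cdc42), Wnt9a (a Wnt ligand), Slc45a4, Rnf11 (a RING finger protein) and Zfp715 (a zinc finger protein) completed the 10 largest rises, with log2 fold changes between 6.13 and 6.66. The fallers also included Prr18, from 41.5 ± 3.1 to 0.193 ± 0.020 FPKM, and Manba, the lysosomal beta-mannosidase, from 30.9 ± 3.4 to 1.51 ± 0.18. Chac2, an enzyme of glutathione breakdown, fell from 18.2 ± 2.8 to 0.622 ± 0.17, Tceal8 from 14.5 ± 0.79 to 0.391 ± 0.16 and Iqcf5 from 44.7 ± 2.0 to 3.45 ± 2.1. Defb48, a beta-defensin, was at 15.7 ± 2.9 FPKM in WT and was listed at 0 in the 4 GTMut and the 4 D272Mut libraries. Oog1, an oogenesin, fell from 129 ± 16 to 3.93 ± 4.0, but it belongs to a multi-copy family and overlaps 8 other tested genes, so its reads could be split among copies. Chac2, Setdb1, Trp53bp1 and Map2k1 each overlap another tested gene. Libraries of WT and GTMut did not overlap for 72.9% of the tested genes, where chance gives 2.86%.

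The lists of oocyte genes in this paragraph had more members that fell than rose in GTMut. Of 20 tested genes of a list of zona pellucida and oocyte-secreted factors that also holds oocyte genes of other kinds, such as Rfpl4 and Oog3 (the zona list below), 19 fell, 0 rose and 1 did not pass. Rfpl4 fell from 1698 ± 43 to 322 ± 13 FPKM, Oog3 from 1016 ± 47 to 291 ± 17, Bmp6, a growth factor, from 175 ± 7.3 to 90.9 ± 1.8 and Oosp1, an oocyte-secreted protein, from 589 ± 26 to 279 ± 11. Of 24 maternal effect genes 13 fell and 6 rose. Dnmt1, the maintenance DNA methyltransferase, fell from 273 ± 7.2 to 73.6 ± 3.8, its partner Uhrf1 from 246 ± 6.1 to 117 ± 4.2 and Btg4, an adaptor of maternal mRNA deadenylation, from 755 ± 24 to 322 ± 14. Khdc3, a member of the subcortical maternal complex, rose from 644 ± 25 to 1711 ± 66. Of 15 genes of cAMP and cGMP meiotic arrest 11 fell and 2 rose (9 and 4 under median-ratio rescaling, 11 and 3 under quantile normalization). Gpr3, the receptor that keeps cAMP high in the arrested oocyte, fell from 157 ± 3.9 to 63.0 ± 4.0, Pde3a, the phosphodiesterase that lowers it, from 41.3 ± 2.0 to 24.4 ± 0.32, Rgs2 from 356 ± 13 to 230 ± 6.2 and Akap7, an anchor of protein kinase A, from 30.0 ± 1.5 to 13.1 ± 0.41. Of 35 genes of meiotic resumption and the cell cycle 19 fell and 9 rose. Aurkc, the Aurora kinase typical of germ cells, fell from 76.9 ± 2.8 to 10.8 ± 0.68, Mapk3, a MAP kinase, from 104 ± 1.8 to 38.6 ± 3.1 and Fbxo43, an inhibitor of the anaphase-promoting complex, from 60.8 ± 2.1 to 29.5 ± 1.0, while Wee1, an inhibitory kinase of CDK1, rose from 17.2 ± 0.78 to 92.5 ± 3.2.

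Lists of RNA regulators went both ways in GTMut. Of 40 mRNA decay genes 24 fell and 9 rose, and the 4 members with the smallest p all rose: Lsm1, a decapping cofactor, from 7.78 ± 0.50 to 54.8 ± 1.5 FPKM, Smg5, a nonsense-mediated decay factor, from 3.04 ± 0.28 to 21.7 ± 1.1, Edc3, an enhancer of decapping, from 0.580 ± 0.12 to 15.3 ± 1.4 and Ago2, the slicer Argonaute, from 2.26 ± 0.24 to 14.2 ± 1.2. Of 25 genes of maternal mRNA storage and translation 13 rose and 12 fell. Zfp36l2, which binds AU-rich elements, rose from 6.60 ± 0.52 to 341 ± 27 and Larp1 from 3.01 ± 0.34 to 24.6 ± 1.4, while Lsm14b fell from 791 ± 11 to 348 ± 9.7. Of 29 piRNA and retrotransposon control genes 15 fell and 9 rose. Piwil2 rose from 0.798 ± 0.13 to 17.7 ± 0.86, Ddx4, the germ cell helicase, from 11.8 ± 1.0 to 79.6 ± 2.8 and Tex19.1 from 89.5 ± 4.8 to 549 ± 36, while Setdb1, a histone H3 lysine methyltransferase, fell from 76.2 ± 1.0 to 46 ± 1.3. Of 16 oocyte transcription factor and growth genes 7 rose and 9 fell (7 and 7 under median-ratio rescaling and under quantile normalization). Yy1 rose from 12.6 ± 1.4 to 188 ± 10, Tbpl2, the TBP paralog of oocytes, from 5.19 ± 0.85 to 106 ± 6.7 and Gtf2a1l from 32.9 ± 1.7 to 115 ± 3.1, while Obox2 fell from 1503 ± 63 to 464 ± 16. Of 22 tested PP2A subunits and shugoshins 7 rose and 10 fell (7 and 7 under median-ratio rescaling, 7 and 14 under quantile normalization). The list's median log2 fold change of -0.11 and its mean of 0.33 differed in sign. Besides Ppp2cb, the other catalytic subunit gene Ppp2ca rose from 116 ± 4.3 to 221 ± 4.3, and the regulatory subunit gene Ppp2r5e from 19.6 ± 1.0 to 66.0 ± 5.0. The scaffold subunit gene Ppp2r1b rose from 7.26 ± 0.43 to 24.7 ± 1.7, with another tested gene overlapping it.

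Lists of stress and housekeeping genes went different ways in GTMut. Of 27 unfolded protein and heat shock genes 19 rose and 6 fell. Dnajb1, a heat shock cochaperone, rose from 142 ± 3.0 to 386 ± 1.7 FPKM, Hspa1b, an inducible Hsp70, from 7.73 ± 0.78 to 77.4 ± 3.7, Xbp1, a transcription factor of the unfolded protein response, from 0.943 ± 0.33 to 43.1 ± 3.5 and Chac1, a target of ATF4, from 4.52 ± 0.65 to 73.0 ± 3.9. Of 12 immediate early genes 8 rose and 2 fell. Ier2 rose from 3.06 ± 0.56 to 76.6 ± 7.9, Klf4 from 8.80 ± 0.64 to 43.2 ± 2.8 and Atf3 from 1.75 ± 0.32 to 9.17 ± 0.36, while Dusp1, a MAP kinase phosphatase, fell from 91.5 ± 4.9 to 35.2 ± 1.1. Of 26 p53 target and cell death genes 13 rose and 5 fell (10 and 10 under quantile normalization). Mcl1, an anti-apoptotic BCL2 relative, rose from 12.6 ± 1.8 to 446 ± 17, Aen, a p53-induced nuclease, from 7.78 ± 0.65 to 68.8 ± 1.2 and Gadd45b from 3.62 ± 1.2 to 18.2 ± 1.3, while Trp53inp1 fell from 19.4 ± 1.1 to 10.2 ± 0.61. Of 27 DNA damage and repair genes 17 fell and 6 rose. Trp53bp1 fell from 22.6 ± 0.55 to 8.21 ± 0.29, Brca2 from 26.1 ± 1.1 to 12.4 ± 0.98, its partner Palb2 from 14.9 ± 0.50 to 4.83 ± 0.61 and Brca1 from 34.8 ± 1.2 to 19.6 ± 1.1. Of 13 interferon and nucleic acid response genes 4 rose, among them the RNA editing enzyme gene Adar from 16.2 ± 0.56 to 50.1 ± 1.1, and 6 fell, among them the transcription factor gene Irf1 from 96.6 ± 2.0 to 51.5 ± 0.95. Of 79 cytosolic ribosomal protein genes 16 rose and 29 fell (20 and 21 under median-ratio rescaling, 8 and 44 under quantile normalization), with Rpl10l rising from 6.37 ± 1.2 to 32.2 ± 2.5. Of 77 oxidative phosphorylation genes 12 rose and 28 fell (14 and 24 under median-ratio rescaling, 8 and 43 under quantile normalization), with Uqcrc1 rising from 0.600 ± 0.31 to 7.71 ± 0.44 and Sdha falling from 21.8 ± 1.0 to 9.88 ± 0.80. Of 28 replication-dependent histone genes 19 did not pass, 4 rose and 5 fell (5 and 5 under median-ratio rescaling), with Hist3h2ba falling from 42.0 ± 7.2 to 9.26 ± 3.7 and Hist1h4i rising from 12.5 ± 2.6 to 39.9 ± 6.7. Histone and ribosomal protein genes have near-identical copies that could share reads.

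The set test camera, with a preset correlation between genes, separated 2 of the 19 lists from the other genes in GTMut. They were the zona list, lower at an adjusted p = 1.89e-05, and the unfolded protein and heat shock genes, higher at an adjusted p = 0.0215. Neither call held with an estimated correlation, where the adjusted p = 0.107 for each and 3 of the 19 lists had an unadjusted p under the threshold. The zona list was also not called after quantile normalization, an alternative chosen after seeing the data, with 15 of 20 genes lower, 2 higher and an adjusted p = 0.0938. The heat shock list was not called among genes with a mean FPKM of at least 5, where its adjusted p = 0.0979. Over the 18 alternatives run for lists, the camera adjusted p ran from 1.13e-05 to 0.107 for the zona list. For the heat shock list it ran from 0.00128 to 0.107. Of the 35 splits of these 8 libraries, some of which keep part of the genotype difference, 7 called at least 2 lists, the real one included. Median and mean log2 fold change differed in sign, with a camera direction of down, for the oocyte transcription factor list (-0.16 and 0.45), the piRNA list (-0.22 and 0.01), the histones (-0.05 and 0.01) and the granulosa markers (-0.22 and 0.13) as they did for the PP2A list. For the other 17 lists the camera adjusted p lay between 0.0979 and 0.900. Adjusted over the list alone, the number of changed members equalled that over all genes in each list except 4, with 29 in meiotic resumption and the cell cycle, 44 among ribosomal proteins, 38 in oxidative phosphorylation and 4 among other ovarian cell markers. Over all genes these were 28, 45, 40 and 5. In the labels nothing says that the 4 libraries of a genotype came from separate animals, so the p-values measure the spread between these libraries. No batch or date is labelled, so no value within batches can be given. The median log2 fold change over all tested genes was -0.02, with 49.4% of the changed genes higher. It moved to 0.06 under median-ratio rescaling, which gave 5386 higher and 4501 lower genes (54.5% higher), and to -0.23 under quantile normalization, which gave 4105 and 6369 (39.2% higher).

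**Figure D2:**
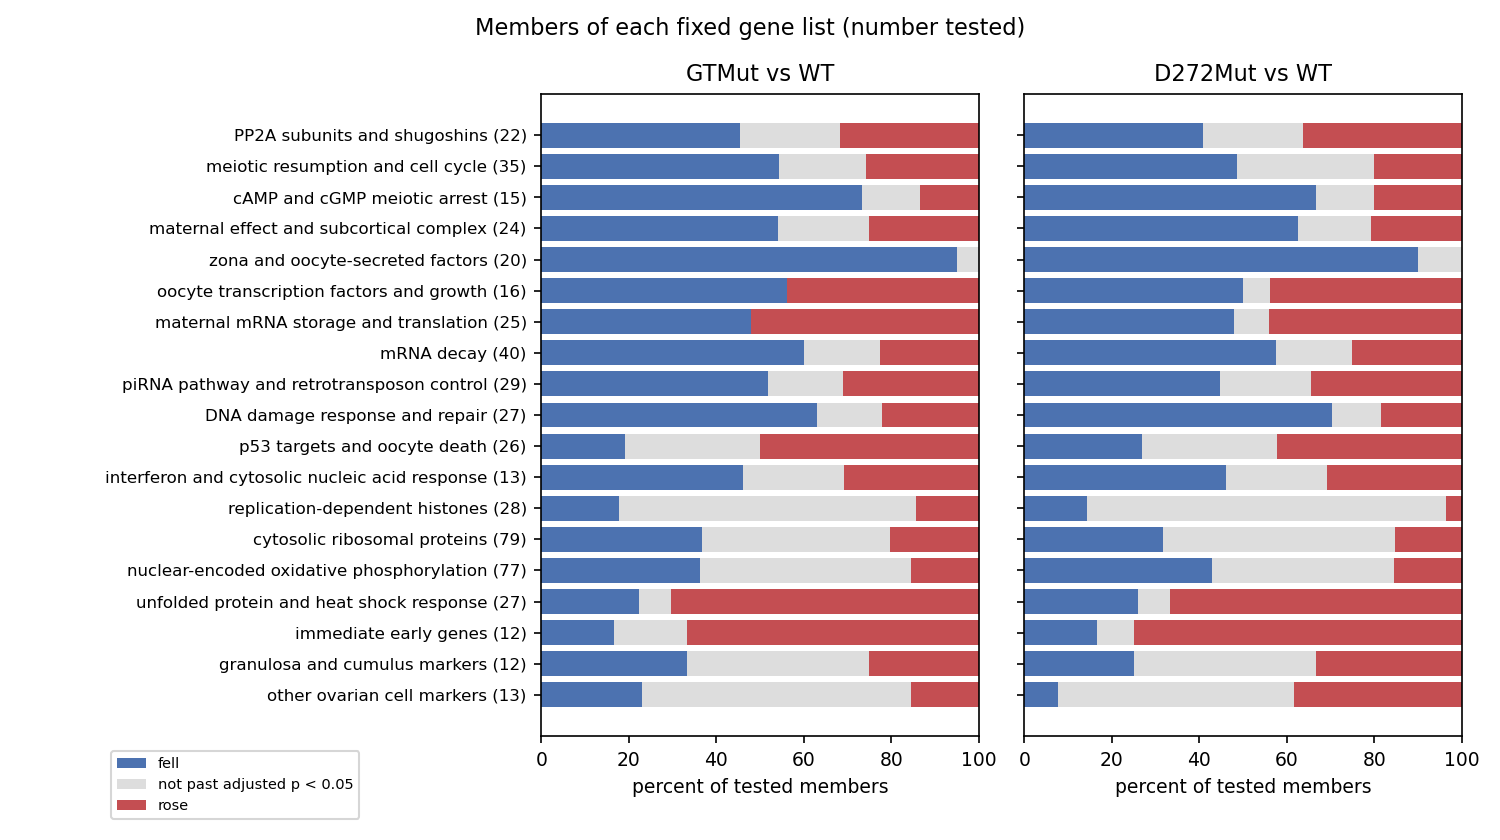
Percent of the tested members of each of 19 gene lists (horizontal axes) that fell, rose or did not pass an adjusted p under 0.05 in GTMut against WT and in D272Mut against WT, with the number of tested members in brackets. The list named zona and oocyte-secreted factors, which also holds other oocyte genes, has no riser in either mutant, with 19 and 18 of 20 members lower.

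The comparison of D272Mut with WT asks the same for the D272 mutant. Genes low in WT were again the largest risers. Dio3 reached 311 ± 16 FPKM, Id3 684 ± 39, Cdc42ep4 274 ± 11 (2.40 ± 0.36 in WT) and Tex19.2 430 ± 48, and Fzd5 reached 116 ± 12. Ier2 rose to 189 ± 9.5 and the zinc finger gene Zfp707 from 10.7 ± 1.0 to 538 ± 19. Pnpla3, a lipase of lipid droplets, fell from 134 ± 8.9 to 1.59 ± 0.42, although it stood at 137 ± 7.2 in GTMut. Manba fell to 0.468 ± 0.18 and Slc39a8 to 0.0896 ± 0.078.

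In all, 4710 genes were higher and 5121 lower in D272Mut among the 12980 tested with limma at an adjusted p under 0.05. At least 2-fold rises numbered 2324 and such falls 766, and 140 genes rose and 8 fell at least 16-fold. Wnt9a, Slc45a4 and Fam109a were also among the 10 largest rises, with log2 fold changes of 6.04 ± 0.10, 6.00 ± 0.06 and 5.90 ± 0.06. Gsto2, a glutathione transferase, was at 9.76 ± 1.2 FPKM in WT, 2.38 ± 0.63 in GTMut and was listed at 0 in the 4 D272Mut libraries. Fam124a, at 8.81 ± 0.75 in WT, was also listed at 0 there. Arhgef15 fell from 7.88 ± 1.0 to 0.0355 ± 0.041, Chac2 to 1.35 ± 0.38 and Tmem87a from 13.6 ± 1.1 to 1.09 ± 0.32, with 2 tested genes overlapping it. Oog1 was at 0.550 ± 0.81, with 2 of 4 libraries listed at 0. Libraries of D272Mut and WT did not overlap for 69.1% of the tested genes.

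The same lists were counted in D272Mut. Of 20 genes of the zona list 18 fell and 0 rose, with Oog3 at 297 ± 24, Oog2 at 147 ± 12 (374 ± 11 in WT), Rfpl4 at 592 ± 62 and Bmp6 at 102 ± 0.89 FPKM. Of 24 maternal effect genes 15 fell and 5 rose, with Nlrp4f falling from 557 ± 14 to 264 ± 7.7, Dnmt1 to 84.7 ± 7.7 and Uhrf1 to 121 ± 4.4, and with Khdc3 rising to 1701 ± 87. Of 27 DNA damage and repair genes 19 fell and 5 rose, with Trp53bp1 falling to 12.2 ± 0.29 and H2afx, the histone variant of DNA breaks, from 207 ± 9.3 to 136 ± 4.2. Of 27 unfolded protein and heat shock genes 18 rose and 7 fell, with Dnajb1 at 385 ± 8.4, Hspa1b at 96.6 ± 9.1, Xbp1 at 35.7 ± 1.9 and Chac1 at 46.3 ± 4.2. Of 12 immediate early genes 9 rose and 2 fell, Ier2 and Klf4 (36.9 ± 2.5) among the risers. Of 26 p53 target and cell death genes 11 rose and 7 fell (7 and 10 under quantile normalization), with Mcl1 rising to 314 ± 17 and Aen to 66.4 ± 2.2. Of 35 meiotic and cell cycle genes 7 rose and 17 fell, with Wee1 rising to 86.1 ± 8.1 and Map2k1, a MAP kinase kinase, falling from 131 ± 3.2 to 83.1 ± 3.1. Of 15 genes of meiotic arrest 3 rose and 10 fell (5 and 9 under median-ratio rescaling, 3 and 11 under quantile normalization), with Rgs2 falling to 240 ± 4.2, Akap7 to 14.8 ± 1.6 and Pde3a to 26.6 ± 1.8. Of 40 mRNA decay genes 10 rose and 23 fell, with Lsm1 at 54.3 ± 2.6, Smg5 at 19 ± 0.56 and Ago2 at 15.3 ± 1.3, each higher than in WT. Of 25 storage and translation genes 11 rose and 12 fell (13 and 12 under median-ratio rescaling), with Zfp36l2 rising to 269 ± 18 and Larp1 to 42.7 ± 3.0. Of 29 piRNA and retrotransposon genes 10 rose and 13 fell, with Piwil2 rising to 19 ± 1.4 and Ddx4 to 73.0 ± 6.3. Of 16 oocyte transcription factor genes 7 rose and 8 fell (7 and 7 under median-ratio rescaling, 6 and 5 under quantile normalization), with Yy1 rising to 155 ± 7.4 and Gtf2a1l to 120 ± 5.7. Of 22 PP2A and shugoshin genes 8 rose and 9 fell (10 and 6 under median-ratio rescaling, 8 and 12 under quantile normalization). Ppp2r1b rose to 28.0 ± 1.9 and Ppp2r5e to 60.0 ± 3.4. Of 13 interferon and nucleic acid response genes 4 rose and 6 fell, with Adar rising to 44.9 ± 3.0 and Irf1 falling to 55.5 ± 1.7. Of 28 histone genes 23 did not pass, 1 rose and 4 fell (3 and 4 under median-ratio rescaling, 0 and 8 under quantile normalization), with Hist1h2bc falling from 172 ± 19 to 98.9 ± 5.6. Of 79 ribosomal protein genes 12 rose and 25 fell (17 and 17 under median-ratio rescaling, 10 and 42 under quantile normalization), with Rpl7l1 rising from 5.84 ± 0.45 to 19.6 ± 1.6. Of 77 oxidative phosphorylation genes 12 rose and 33 fell (14 and 23 under median-ratio rescaling, 9 and 48 under quantile normalization), with Uqcrc1 rising to 8.63 ± 0.72.

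In D272Mut, camera with a preset correlation called 4 of the 19 lists. The zona list was lower (adjusted p = 2.17e-05), as were the maternal effect genes and the DNA damage and repair genes, and the unfolded protein and heat shock genes were higher, each at an adjusted p = 0.0427. With an estimated correlation 0 lists were called by camera, 3 had an unadjusted p under the threshold, and the adjusted p was 0.118, 0.118, 0.291 and 0.118 in that order. Without D272Mut replicate 2 only the zona list and the DNA damage list remained, since the maternal effect and heat shock lists each had an adjusted p = 0.0517. The maternal effect call was also lost under median-ratio rescaling (adjusted p = 0.0632) and with the replicate block (adjusted p = 0.0511), and both it and the heat shock call among genes with a mean FPKM of at least 5 (adjusted p = 0.124 for each). Under quantile normalization, chosen for the lists after seeing the data, the heat shock list alone was called, at an adjusted p = 0.0104, against 0.0833 for the zona list, 0.612 for the maternal effect genes and 0.0715 for DNA damage and repair. Over the 18 alternatives run for lists, the camera adjusted p ran from 1.06e-05 to 0.118 for the zona list. For the maternal effect list it ran from 0.0392 to 0.612, for the DNA damage list from 0.0374 to 0.291 and for the heat shock list from 0.0104 to 0.124. Of the 35 splits of these 8 libraries, some of which keep part of the genotype difference, 4 called at least 4 lists, the real one included. Median and mean differed in sign for the PP2A list (-0.08 and 0.36), the oocyte transcription factors (-0.03 and 0.50) and the storage and translation list (-0.03 and 0.47), each with a camera direction of up, and for the decay list (-0.35 and 0.04) and the piRNA list (-0.13 and 0.11), each with a direction of down. Adjusted over the list alone, changed members numbered 23 in meiotic resumption and the cell cycle, 21 among maternal effect genes, 4 among histones, 36 among ribosomal proteins and 42 in oxidative phosphorylation, against 24, 20, 5, 37 and 45 over all genes, with equal numbers in the other lists. The median log2 fold change over all genes was -0.05, with 47.9% of the changed genes higher. It was 0.04 under median-ratio rescaling, which gave 5158 higher and 4426 lower genes (53.8% higher), and -0.25 under quantile normalization, which gave 3865 and 6471 (37.4% higher).

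The mutants were compared with each other to ask where the alleles differ. Besides Marf1, Bfar, the bifunctional apoptosis regulator gene, differed, with 18.6 ± 1.3 FPKM in WT, 5.46 ± 0.67 in GTMut and 95.8 ± 3.2 in D272Mut. Pnpla3 was lower in D272Mut than in GTMut by a log2 fold change of -5.75 ± 0.09, and Trim25, an RNA-binding ubiquitin ligase, stood at 0.149 ± 0.096 in WT, 24.4 ± 1.6 in GTMut and 0.526 ± 0.34 in D272Mut. Prr18 stood at 0.193 ± 0.020 in GTMut and 30.6 ± 5.0 in D272Mut. Aurkc fell less in D272Mut (47.7 ± 1.5) than in GTMut (10.8 ± 0.68), as did Gpd1l, with 78.3 ± 6.5 in WT, 9.72 ± 0.62 in GTMut and 54.5 ± 0.84 in D272Mut, and Stt3b, a catalytic subunit of the oligosaccharyltransferase, with 238 ± 4.6, 40.7 ± 2.2 and 116 ± 6.1.

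Of the 12980 genes, 2508 were higher and 2626 lower in D272Mut than in GTMut with limma at an adjusted p under 0.05 (2616 and 2516 under median-ratio rescaling, 2630 and 2529 under quantile normalization). At least 2-fold differences numbered 201 and 235. Higher in D272Mut were also Tmem51 (0.295 ± 0.15 in GTMut and 11.1 ± 1.2 in D272Mut), Cntn2, a contactin (0.186 ± 0.065 and 5.39 ± 0.69), Zfp111 (5.90 ± 1.2 and 34.8 ± 1.4), Iqcf5 (3.45 ± 2.1 and 21.5 ± 4.1) and Sfta2 (0.102 ± 0.20 and 5.53 ± 2.6). The olfactory receptor gene Olfr206 was listed at 0 in the 4 GTMut libraries and stood at 5.21 ± 0.86 in D272Mut. Lower in D272Mut were Spesp1, a sperm equatorial segment gene (9.84 ± 1.1 in GTMut and 0.0603 ± 0.044 in D272Mut), Draxin, an axon guidance gene (16.7 ± 2.9 and 0.930 ± 0.21), and Rundc1 (55.5 ± 2.4 and 6.66 ± 1.3, with another tested gene overlapping it). Prr15l (14.9 ± 1.4 and 1.73 ± 0.49), Stk32a (5.70 ± 0.63 and 0.165 ± 0.13), Tagap (28.9 ± 1.5 and 4.29 ± 0.35), Pxdn, the peroxidasin gene (36.8 ± 1.3 and 5.92 ± 0.58) and Ralgds, a Ral exchange factor (53.1 ± 0.96 and 15.1 ± 0.56), were lower too. Lancl3 stood at 4.72 ± 0.62 in GTMut and was listed at 0 in 3 of 4 D272Mut libraries and in the 4 WT libraries. Among the 10 genes with the smallest p were also the unnamed gene models 5730507C01Rik (14.1 ± 1.1 in WT, 0.0762 ± 0.052 in GTMut and 29.2 ± 0.78 in D272Mut) and A930015D03Rik (69.3 ± 1.4, 105 ± 2.7 and 3.30 ± 1.2), the latter overlapping another tested gene. Of 20 tested genes within 2 Mb of Marf1, Bfar was the 1 that differed at least 2-fold between the mutants, against 3.36% of all tested genes. Bfar lies 406 kb from Marf1, on the plus strand, and overlaps the tested gene 3110001I22Rik.

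No list was called by camera in the difference between the mutants, where the lowest adjusted p of the 19 lists was 0.222 with the preset and 0.488 with an estimated correlation, and the unadjusted p was under 0.05 for 1 list, the other ovarian cell markers at 0.0117. Median and mean differed in sign there for the maternal effect list (0.01 and -0.02), the storage and translation list (-0.05 and 0.02), the interferon list (0.01 and -0.03) and the oxidative phosphorylation list (-0.02 and 0.02), with a camera direction of down, and for the immediate early genes (-0.11 and 0.10), with a direction of up. Single members differed in each of the lists. Of 35 meiotic and cell cycle genes 11 were higher and 5 lower in D272Mut, with Mapk3 at 59.1 ± 2.0 against 38.6 ± 3.1 in GTMut. Of 15 genes of meiotic arrest 4 were higher and 1 lower (5 and 2 under quantile normalization), with Gpr3 at 98.6 ± 11 against 63.0 ± 4.0. Of 20 genes of the zona list 8 were higher and 6 lower, with Rfpl4 and Oosp1 (357 ± 21 against 279 ± 11) higher. Of 24 maternal effect genes 4 were higher, among them Btg4 (455 ± 8.8 against 322 ± 14), and 8 lower. Of 16 oocyte transcription factor genes 6 were higher, among them Obox2 (836 ± 26 against 464 ± 16), and 4 lower, among them Tbpl2 (47.9 ± 1.4 against 106 ± 6.7). Of 22 PP2A and shugoshin genes 8 were higher and 2 lower, with Ppp2cb and Ppp2ca (183 ± 6.1 against 221 ± 4.3) the lower ones. Of 25 storage and translation genes 7 were higher, Larp1 among them, and 9 lower (7 and 7 under quantile normalization). Of 40 mRNA decay genes 12 were higher and 4 lower, Edc3 (7.82 ± 1.2 against 15.3 ± 1.4) among the lower. Of 29 piRNA and retrotransposon genes 6 were higher and 4 lower, Exd1 (11.6 ± 0.77 against 16.5 ± 1.1) among the lower. Of 27 DNA damage genes 5 were higher, Trp53bp1 among them, and 6 lower (6 and 6 under median-ratio rescaling), among them Parp1 (5.86 ± 0.36 against 9.05 ± 0.56). Of 26 p53 target genes 4 were higher and 7 lower, Mcl1 among the lower. Of 13 interferon response genes 1 was higher and 2 lower, and 0 were called by limma when adjusted over the list alone. Of 28 histone genes 2 were higher and 3 lower, with Hist1h4i lower (11.8 ± 2.6 against 39.9 ± 6.7) and Hist3h2ba higher (30.5 ± 7.6 against 9.26 ± 3.7). Of 79 ribosomal protein genes 12 were higher and 5 lower, with Rpl29 lower (14.2 ± 1.6 against 74.6 ± 9.0). Of 77 oxidative phosphorylation genes 7 were higher, among them Sdha (14.5 ± 1.3 against 9.88 ± 0.80), and 12 lower. Of 27 heat shock genes 6 were higher and 10 lower, with Hsp90ab1 lower (137 ± 3.8 against 186 ± 2.9). Of 12 immediate early genes 5 were higher, among them Junb (9.68 ± 0.66 against 2.29 ± 0.51) and Ier2, and 6 lower. Adjusted over the list alone, calls in the mutants' difference numbered 13 among ribosomal proteins (17 over all genes), 9 in oxidative phosphorylation (19), 12 among PP2A and shugoshin genes (10), 15 in the zona list (14), 11 among oocyte transcription factors (10), 17 in storage and translation (16) and 17 in the heat shock list (16), and were as over all genes in the remaining lists except the interferon list given above.

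Changes of the mutants were set side by side because both were measured against the same WT libraries. Genes that rose in both, such as Id3, Zfp707, Dio3, Khdc3 and Ppp2cb, numbered 4214, and genes that fell in both, such as Slc39a8, Manba, Oog3 and Dnmt1, numbered 4369 (4594 and 3735 under median-ratio rescaling). Independent lists of these sizes would share 1805 and 2007. In 100 simulations of unchanged groups, with all libraries drawn around the WT gene means, no gene was shared. The simulated noise was independent between genes, which makes shared calls unlikely from the start. In opposite directions went 182 genes. Of those, 93 were lower in GTMut and higher in D272Mut, and 89 the reverse. At least 2-fold in each direction these were Marf1, Bfar, Tmem51, Draxin and Ccdc3, which was named after its values were seen (21.9 ± 1.5 FPKM in WT, 45.6 ± 3.2 in GTMut and 9.81 ± 1.3 in D272Mut). Across genes, which are not independent replicates, the log2 fold changes of the mutants correlated at r = 0.922 (Spearman rho 0.912), and at 0.885 to 0.897 when the mutants were set against different pairs of WT libraries. Unchanged groups simulated in that way, against shared simulated WT libraries, gave a mean r of 0.508 (at most 0.773). Their mean covariance was 0.0272 (at most 0.0617), against an observed covariance of 1.33. Of the genes that rose in both mutants, 1269 were lower in D272Mut than in GTMut, as Fzd5 and Rnf11 (159 ± 20 FPKM against 414 ± 21) were, 545 were higher, as Ier2 was, and 2400 did not differ by the test. Of those that fell in both, 1235 were higher in D272Mut, as Aurkc, Cdo1 (22.6 ± 3.6 against 6.76 ± 1.8) and Stt3b were, 394 were lower, as Manba was, and 2740 did not differ by the test.

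**Figure D3:**
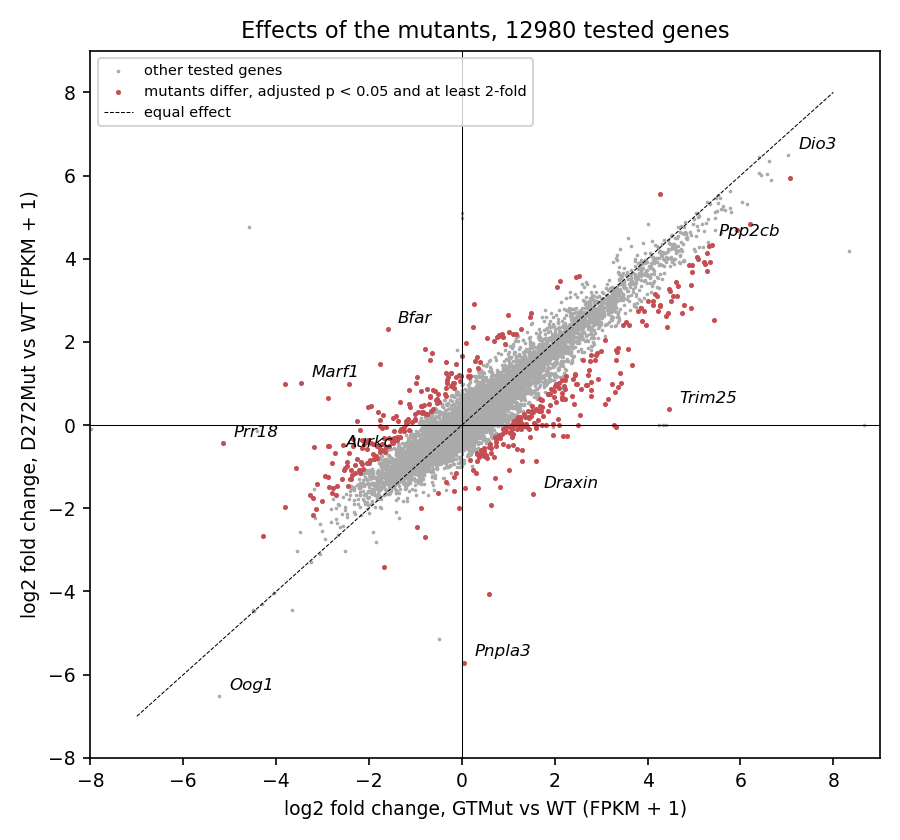
Log2 fold change on the log2(FPKM + 1) scale in D272Mut against WT (vertical axis) and in GTMut against WT (horizontal axis), a point per tested gene, with genes that differ at least 2-fold between the mutants in red and 4 of 12980 genes outside the axis range of -8 to 9. Most points lie along the diagonal of equal effects (r = 0.922), and Marf1, Bfar, Prr18, Trim25, Draxin and Pnpla3 lie off it.

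Levels of markers of other ovarian cells ran from low, as for Pdgfra, to high, as for Serpine2 and Nr5a2. Of 25 listed granulosa and cumulus markers 12 were tested, and of 26 other markers 13. The rest had no library at an FPKM of at least 1 or no matching symbol. Of 12 tested granulosa and cumulus markers, 3 rose and 4 fell in GTMut (3 and 6 under quantile normalization) and 4 rose and 3 fell in D272Mut (4 and 4 there under quantile normalization). Serpine2 stood at 112 ± 2.7 FPKM in WT, 107 ± 3.7 in GTMut and 83.2 ± 6.3 in D272Mut. Nr5a2 was higher in both mutants (26.5 ± 1.0, 134 ± 5.5 and 118 ± 1.7), as was Kitl (2.63 ± 0.46, 11.7 ± 1.3 and 11.6 ± 0.81), and Cyp19a1, the aromatase gene, was lower in both (11.7 ± 1.2, 4.90 ± 0.49 and 6.53 ± 0.77). Of 13 other markers 2 rose and 3 fell in GTMut (2 and 2 under median-ratio rescaling, 1 and 7 under quantile normalization), and 5 rose and 1 fell in D272Mut (5 and 4 under quantile normalization). Pecam1, an endothelial marker, was lower in both mutants (20.7 ± 1.1, 11.4 ± 0.39 and 11.7 ± 1.3), Pdgfra, a stromal marker, was higher but low throughout (0.265 ± 0.050, 0.989 ± 0.12 and 0.863 ± 0.099), and Krt8, an epithelial keratin, was highest in D272Mut (5.29 ± 0.71, 8.24 ± 1.6 and 16.6 ± 2.4). The Krt8 rise in GTMut was not called after quantile normalization (adjusted p = 0.146, in a range of 0.000423 to 0.146 over its alternatives). C1qb, a macrophage marker, stood at 18.3 ± 2.0 in WT, 14.5 ± 2.7 in GTMut and 40.0 ± 4.1 in D272Mut, and its lower level in GTMut was not called after median-ratio rescaling (adjusted p = 0.117) or without WT replicate 3, WT replicate 4 or GTMut replicate 3 (adjusted p = 0.0689, 0.0797 and 0.0783), with a range over its alternatives of 0.000719 to 0.117. Between the mutants 3 granulosa markers were higher and 3 lower in D272Mut (3 and 2 under quantile normalization), and 5 other markers were higher and 0 lower.

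The authors' deposited table of cuffdiff results gave 8972, 8571 and 4488 genes at q under 0.05 for GTMut against WT, D272Mut against WT and the mutants against each other. Of these, 97.7%, 97.3% and 91.5% were also called by limma, all with the same sign. For Ppp2cb the authors' deposited table gave log2 ratios of 6.10 and 5.21 in GTMut and D272Mut over WT, and for Marf1 -4.13 and 1.11. The authors' deposited q was above the threshold for some genes called here, among them Oog1 in both mutants (0.204 and 0.101), Slc39a8 (0.0534) and Fam124a (0.256) in GTMut, Arhgef15 (0.238) and Trim25 in D272Mut and Pdgfra in both mutants. The Trim25 rise in D272Mut was itself not called after quantile normalization (adjusted p = 0.407) or without D272Mut replicate 1 or WT replicate 2 (adjusted p = 0.0555 and 0.0503), with a range over its alternatives of 0.00252 to 0.407. In the difference between the mutants the genes above the authors' threshold included Manba, Chac2, Sfta2 (0.101), Lancl3 (0.118) and 5730507C01Rik (0.117).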

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

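Among the tests here, those of granulosa RNA were chosen only after the result was seen, while the splits of the libraries and the test of scaling were planned.

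Both mutants differed from WT in largely the same direction, with 4214 genes higher and 4369 lower in both (4594 and 3735 after median-ratio rescaling), Id3, Dio3 and Ppp2cb among the higher and Dnmt1 and Manba among the lower. Of the genes called in both in the same direction, 92.8% stayed so after that rescaling. Its factors ran only from 0.977 (D272Mut replicate 2) to 1.07 (WT replicate 1). The result therefore argues against a scaling difference of that size as the whole source, and it cannot decide about larger ones. The shared calls were not counted under quantile normalization. RNA from granulosa cells is argued against as the whole source as well, since 3 of 12 tested granulosa markers rose in GTMut and 4 in D272Mut, and Cyp19a1 fell in both, from 11.7 FPKM in WT to 4.90 in GTMut and 6.53 in D272Mut. Serpine2, the most abundant in WT, was at 112, 107 and 83.2. A small share stays open in both mutants, as Nr5a2, the most abundant there, rose from 26.5 to 134 and 118, Kitl from 2.63 to 11.7 and 11.6 and Inhba from 0.111 to 1.79 and 0.999, and Gja1 rose in D272Mut alone, from 0.859 to 3.30. The labels name no batch or date, so none was weighed. A loss of MARF1 function common to both alleles may account for the pattern, as a hypothesis that stays untested.

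Other splits of the libraries into groups of the same sizes were counted. For the genes changed in GTMut, only the real split, 1 of 35, gave as many as 10059, and the highest of the others gave 1. For D272Mut it was again 1 of 35 (9831, highest other 1), and for the difference between the mutants 1 of 35 (5134, highest other 1). For genes called in both mutants in the same direction it was 1 of 100 drawn splits of the 12 libraries (8583, highest other 1). These 4 counts were thus tied to the real grouping of these libraries. A mixed split places the genotype difference in the spread within groups, so it was bound to call few genes. The splits therefore cannot exclude chance differences between animals, pools or batches, which are not labelled. Chance is also not excluded for the gene list calls, and the splits cannot decide it. As many lists as the 2 of GTMut were called by 7 of 35 splits, with 3 as the highest other. As many as the 4 of D272Mut were called by 4 of 35, with 5 as the highest other. Splits with 3 libraries of a genotype in a group keep part of the genotype difference, so these counts are no reference free of it. The other splits that called as many lists as the real one in D272Mut were all of that kind.

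The mutants' effects went in opposite directions for 182 genes. All of them also differed between the mutants by limma, which adds no support, since opposite calls against the same WT libraries nearly fix that result. As log2 differences of D272Mut minus GTMut, Marf1 was at 4.48, Bfar at 3.91, Tmem51 at 3.22, Cntn2 at 2.43 and Zfp111 at 2.39, each lower than WT in GTMut and higher in D272Mut. The same held for 5730507C01Rik at 4.81, Junb at 1.71 and C1qb at 1.41. Olfr206, at 0.833 FPKM in WT and 5.21 in D272Mut, was listed at 0 in the 4 GTMut libraries. Higher than WT in GTMut and lower in D272Mut were Draxin at -3.19, Prr15l at -2.56, Pxdn at -2.45, Ralgds at -1.75, A930015D03Rik at -4.66, Rpl29 at -2.31 and Parp1 at -0.55. Of these, the rise of Cntn2 in D272Mut and that of Parp1 in GTMut were not called after quantile normalization (adjusted p = 0.372, in a range of 0.000239 to 0.372 over its alternatives, and 0.814, in a range of 4.81e-05 to 0.814), and the falls of C1qb in GTMut and Parp1 in D272Mut were not called after median-ratio rescaling (adjusted p = 0.117, in a range of 0.000719 to 0.117, and 0.0973, in a range of 4.6e-06 to 0.0973).

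In 26 of 387 groups of 4 libraries a library stood far from the other 3 by Dixon's gap test, where chance gives 19.4. In WT these were Tceal8 in replicate 3 (13.4 FPKM), Gsto2 in replicate 1 (7.95, others 10.3 to 10.5), Rundc1 in replicate 3 (0.160), Gpr3 in replicate 2 (151, others 158 to 159), Gtf2a1l in replicate 2 (30.3), Smg5 in replicate 2 (2.62), Mcl1 in replicate 3 (15.3), Hist3h2ba in replicate 1 (52.7), Kitl in replicate 4 (1.95) and Rpl7l1 in replicate 3 (6.51). In GTMut these were Iqcf5 in replicate 4 (0.360, others 4.30 to 4.61), Sfta2 in replicate 4 (0.408, others listed at 0), Stt3b in replicate 3 (37.3), Oog3 in replicate 3 (266, others 297 to 303), Dusp1 in replicate 4 (36.8) and Pecam1 in replicate 3 (10.9). GTMut replicate 3 also had fewer genes above 0 (15654) and a lower FPKM sum without small RNA genes (431195) than the other 3. In D272Mut these were Lancl3 in replicate 3 (0.0361, others listed at 0), Aurkc in replicate 3 (45.4), Gadd45b in replicate 3 (13.2), Hspa1b in replicate 1 (83.1), Serpine2 in replicate 1 (73.8), Cyp19a1 in replicate 4 (5.39), Rpl10l in replicate 3 (24.95) and Pdgfra in replicate 1 (0.714).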

How the results depend on the processing

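The alternatives given here were planned except quantile normalization of gene lists and single genes, which was chosen after seeing the data. Counts of changed genes stayed within 1.5 times their value under other pseudocounts, no filter, rescaling, no intensity trend, library weights and fits of only the compared genotypes. At least 2-fold changes numbered 3755 in GTMut (2508 higher, 1247 lower), 3090 in D272Mut (2324 higher, 766 lower) and 436 between the mutants (201 higher, 235 lower), a smaller set by construction. With a mean FPKM of at least 5, where fewer genes are tested, 3298 genes were higher in GTMut, and camera called 1 list in GTMut and 2 in D272Mut. It called 1 and 1 after quantile normalization and 0 and 0 with an estimated correlation, and the cause was not tested. The estimated correlation was above the preset 0.01 for the zona list (0.0963) and the DNA damage list (0.0644). It was below 0.01 for the maternal effect list (0.00105) and the heat shock list (-0.0162), whose unadjusted camera p rose all the same. A larger correlation between genes therefore does not account for the loss of these last calls. Leaving out a library at a time gave 9773 to 10102 changed genes in GTMut, 9517 to 9804 in D272Mut and 4524 to 5094 between the mutants, and 2 to 4 list calls in D272Mut, with 2 without D272Mut replicate 2. The correlation of the mutants' effects was 0.909 with a pseudocount of 0.1 and 0.935 with a mean FPKM of at least 5. The cause of these shifts was not tested. With WT split into pairs of libraries it was 0.890, 0.895, 0.885, 0.897, 0.886 and 0.897. Each mutant then met 2 WT libraries in place of 4, with none in common, which by design tends to lower the correlation. The covariance was 1.30 to 1.31 with these splits, against 1.33 in the main fit. Of 6254 comparisons of single genes with an alternative, 6177 kept direction and side of the threshold, 54 lost and 23 gained a call, and 0 reversed.

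The replicate number as a block gave 10007, 9771 and 4931 changed genes and 3 list calls in D272Mut. Nothing pairs the libraries by that number: the 12 same-number pairs of libraries correlated at -0.585 to 0.145 after removal of genotype means, and 2 of 12 libraries were closest to one with their own number. Pairs of different number correlated at -0.297 to 0.602, highest for WT replicate 1 with GTMut replicate 2. Whether libraries of different genotypes share a factor that the labels do not name was not tested. Absolute depth is unknown, so levels listed at 0 have no upper limit here.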

Other observations

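The tests in this part were chosen only after the result was seen, except the ratio of summed olfactory receptor levels and the tests of marker lists, which were planned.

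The Id family, chosen after its values were seen, was higher in both mutants beyond Id3. Id1 stood at 2.89 ± 0.46 FPKM in WT, 24.3 ± 2.7 in GTMut and 15.4 ± 3.9 in D272Mut (SD, n = 4). Id2 stood at 1.52 ± 0.32, 96.8 ± 7.5 and 43.7 ± 7.6, and Id4 at 0.493 ± 0.066, 3.65 ± 0.63 and 2.50 ± 0.56. As lists, markers of other cells were not called in the difference between the mutants: of 12 granulosa and cumulus markers 3 were higher and 3 lower in D272Mut (camera adjusted p = 0.703; 3 and 2 under quantile normalization), and of 13 other markers 5 were higher and 0 lower (camera adjusted p = 0.222). The most abundant granulosa marker in both mutants, Nr5a2, was at 134 FPKM in GTMut and 118 in D272Mut, and Serpine2, the most abundant in WT, at 107 and 83.2. Members of these lists higher in D272Mut included Lyz2 of myeloid cells at 1.13 ± 0.88 in WT, 0.595 ± 0.11 in GTMut and 5.51 ± 3.4 in D272Mut, Gja1 of cumulus cells at 0.859 ± 0.20, 0.507 ± 0.23 and 3.30 ± 1.5, and C1qa of macrophages at 0.281 ± 0.14, 0.643 ± 0.22 and 2.45 ± 1.2.

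Of 21 tested members of 4 gene families known from the 2-cell embryo, 20 rose in GTMut, 11 rose in D272Mut and 16 were lower in D272Mut than in GTMut. Reads shared between copies of a family would leave its summed level alike, but the sum in GTMut over that in D272Mut was 3.16 for the Zscan4 family (30.7 ± 9.2 against 9.72 ± 1.8 FPKM, two-sided exact permutation p = 0.0286) and 4.67 for the Eif1a-like family (68.3 ± 27 against 14.7 ± 4.7, exact permutation p = 0.0286, the smallest the design allows). For the Tdpoz family (14.9, exact permutation p = 0.0857) and the Usp17l family (2.15, exact permutation p = 0.114) sharing cannot be told apart from a difference, because the libraries overlap.

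Genes that rose had fewer exons: over 11793 protein-coding genes, which are not independent replicates, the slope of the GTMut log2 fold change on log2 exon number was -0.174 (SE 0.0096), and the 196 genes that rose at least 16-fold had a median of 5 exons against 9 for the rest. Transcript length and GC content are argued against as the whole source by a slope of -0.246 after adjustment for them, and level in WT by -0.148 within bins of that level. Genomic DNA in the GTMut libraries would cover each of 1101 olfactory receptor genes alike. Their mean in GTMut was 0.119 ± 0.0098 FPKM (at most 0.134 in a library). By contrast, the 2315 coding genes that rose at least 2-fold there gained a median of 13.3 FPKM, and the 104 of them with 1 exon a median of 10.3. The same comparison was not made for D272Mut. The planned ratio of summed receptor levels, 0.523 in GTMut over WT, decides nothing, since 2 receptors hold 73.3% of the WT sum, and 65 to 99 receptors were above 0 in GTMut libraries against 65 to 78 in WT.

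A hypothesis that genes that rose carry more AU-rich decay elements in the 3' UTR was tested on 11122 genes, 94.3% of the coding genes tested. It was negative: Spearman rho of ATTTA motifs per kb with the GTMut log2 fold change was -0.02 across genes, and 0.0028 for D272Mut.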
